A study of Oryzias latipes with 6 samples.

How the data were processed

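Whole brains of 6 F1 medaka, 3 per lineage, were dissected and frozen, nuclei were released by homogenization, and 10x Chromium 3' single-nucleus libraries were made from each brain, per the labels' protocols. The submitters' processing notes name Cell Ranger without a version. Reads were aligned to a medaka assembly, the 6 libraries were aggregated, and treated fish were compared with controls within each cluster, per the series design text. The clustering method, filters on nuclei, treatment of doublets and free RNA, and the tool and unit of replication of the comparison are not given in the sources used here. All libraries belong to 1 sequencing batch per the labels.

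The authors deposited 14 tables, 1 per cluster, each with 24365 genes and no column that belongs to a single fish. Of these genes, 14025 have a symbol and 10340 only an Ensembl identifier, which the RefSeq gene table used here (assembly ASM223467v1, another build than the authors') does not pair with names. No coordinates are given for that reason. Per the file headers the columns are the log2 fold change, the log2 mean CPM (counts scaled to a common library total), the p-value and the false discovery rate. The column names of the authors' tables are those edgeR writes, but no source used here states the tool. The deposited log2 values appear to carry a prior count. The authors' adjusted p-values equal Benjamini-Hochberg values over all 24365 genes, undetected ones included, to within 4e-15. The fold change was read as BaP lineage over control lineage from the coding of groups in the table names.

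The number of nuclei and the depth were worked out from the authors' deposited tables. Undetected genes share a floor of the log2 mean level in each table (10.03 to 11.50), which gives the mean library size if the prior count is 2 per library. The resulting 684 to 1905 UMIs are of the size of single nuclei. A gene with 1 count has a p-value set by the share of nuclei in its lineage, and a fold change set by the number of nuclei and a prior count of 0.125. Both steps assume the defaults of a negative-binomial exact test on nuclei, which no source states. In simulated tables modelled on clusters 13, 10, 6 and 4 (24365 genes each), the nuclei of both lineages were recovered exactly in all 4. In the table modelled on cluster 4, the direction was recovered for 131 of 131 changed genes. Among genes with enough counts in both lineages, the median error of log2 fold changes without prior counts was 0.017 there. It was 0.043, 0.18 and 0.17 in those modelled on clusters 10, 6 and 13. With the prior counts left in, the errors for clusters 4, 10, 6 and 13 were 0.065, 0.064, 0.20 and 0.19. The simulation made the same assumptions, so it tests the arithmetic and not the assumptions. The same arithmetic gave mean levels per lineage without the prior counts. Depth per fish is unknown, and intervals across fish cannot be given.

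A gene was called where the authors' adjusted p was under 0.05, and no test of single genes was added. Genes in the upper part of mean expression are those above the median of detected genes. The 23 gene lists were fixed before the data were examined, and a list was tested in each cluster with at least 5 detected members. The median log2 fold change of the list was set against 10000 random lists matched on mean expression, drawn with replacement. Gene length and other traits were not matched. The 2-sided tail shares were adjusted by Benjamini-Hochberg over 321 tests of a list in a cluster, as a description of these tables. Of 200 random lists on shuffled fold changes of cluster 1 (18697 genes), 15 had a tail share under 0.05. Symbols were matched without regard to case, with an a or b added or dropped. From the ribosomal protein list, 9 S6 kinase genes that its wording also takes were left out after the values were seen. Marker ratios used genes with at least 10 CPM in the cluster, a limit set after the data were seen. Calculations used Python 3.11 with numpy, pandas and scipy.

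Named genes followed a rule set before the data were examined. It takes the 10 symbols called in the same direction in the most clusters, and the 3 highest and 3 lowest called genes of the 3 clusters with the most calls. It also takes up to 4 called members of each list, AhR and DNA methylation genes whether called or not, and the gene with the smallest adjusted p in each other cluster. fkbp5 and NELL1 fell under it. Of the genes it takes, 1 is not reported here. Alternatives varied the threshold, a minimum fold change, the adjustment, the expression filter, the number of clusters, the correlation, the list statistic and the marker reference. Fits that need values per fish were not run.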

Results

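Nuclei were profiled by droplet-based single-nucleus RNA-seq from the whole brains of 6 adult male Japanese medaka of the F1 generation, aged 6 months. In 3 fish the parents had been kept in solvent (control lineage), and in 3 the parents had been kept for 21 days in 1 µg/L benzo[a]pyrene (BaP), a polycyclic aromatic hydrocarbon formed by combustion (BaP lineage). The F1 fish themselves were raised in clean water, so the comparison asks how brain gene expression differs between offspring of exposed and unexposed parents, within each type of nucleus. The data used here are the authors' deposited tables, which give 1 comparison of the lineages for each of 14 clusters of nuclei, over 24365 genes. Values per fish are not used here, so no difference below has an error or a replicate check across the 3 fish of a lineage. Under assumptions given with the processing, the arithmetic of the authors' deposited tables gave 7512 nuclei in all, 2429 of the control lineage and 5083 of the BaP lineage, with 69 to 1754 nuclei per cluster. This total over 6 fish is below the number of nuclei that the labels name as the target for 1 sample, a gap left unexplained. The mean depth calculated from the authors' deposited tables was 684 to 1905 UMIs (unique molecular identifiers, each marking 1 captured transcript) per nucleus, depending on the cluster. Log2 fold changes are given as BaP lineage over control lineage, a sign read from the coding of the groups in the tables' names and not stated in their headers. They appear to be damped toward 0 by a prior count, which would understate the change of genes with few counts.

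Marker genes fixed before the data were examined placed part of the clusters among known brain cell types, from mean levels in the authors' deposited tables. Cluster 3 was glutamatergic neuron-like, with all 7 detected markers (such as tbr1b and slc17a6b) at 2 times or more their mean in the other clusters. Cluster 5 was cerebellar granule neuron-like with 8 of 10 markers, although control-lineage means alone favored skeletal muscle markers. Cluster 11 was Purkinje or eurydendroid neuron-like with 10 of 14, although the median of the other clusters as reference favored habenula markers. Cluster 2 was thalamic or tectal neuron-like with 7 of 11 markers, although the pituitary hormone gene pomca was its leading gene and control-lineage means alone favored habenula markers. Cluster 9 was radial glia-like with 16 of 19 markers. Cluster 6 carried 12 of 13 oligodendrocyte markers and 4 of 4 markers of Schwann or olfactory ensheathing cells, with mpz and sox10 in both lists, and is called the myelin-gene cluster. Clusters 0, 1, 4, 7, 8, 10, 12 and 13 stayed numbered. Cluster 8 held 17 of 17 endothelial and 4 of 4 erythrocyte markers and was led by erythrocyte genes such as hbbe2 and alas2. Cluster 10 held 4 of 4 glutamatergic and 3 of 6 thalamic or tectal markers, with the thalamic tcf7l2 among its leading genes. Cluster 13 held 8 of 9 fibroblast or meningeal markers but was led by genes of secreted plasma proteins such as ahsg2, apoa1b, apoa2 and tfa. Cluster 1 was led by peptide genes (oxt, sst1.1, npy) and carried 12 of 13 GABAergic, 5 of 5 dopaminergic or noradrenergic and 4 of 4 cholinergic markers, while cluster 7 was led by keratin genes such as krt5, which belong to epithelium.

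At an adjusted p under 0.05, the authors' deposited tables held 394 calls higher and 453 calls lower in the BaP lineage over the 14 clusters, in 557 different genes. Most of these genes, 430, were called in 1 cluster. The excess of lower calls turned without mitochondrially encoded genes (394 higher, 357 lower), at an adjusted p under 0.1 (606 and 577) and with a log2 fold change of at least 1 in size (131 and 98). Cluster 1 had 68 genes higher and 111 lower in the authors' deposited table, and cluster 2 had 32 higher and 140 lower. In cluster 4, 72 genes were higher and 22 lower, in cluster 3, 73 and 10, in cluster 6, 66 and 15, and in cluster 0, 36 and 54, by the authors' deposited tables. Fewer genes were called in cluster 7 (7 higher, 35 lower), cluster 8 (15 and 18), cluster 9 (16 and 11), cluster 5 (4 and 22), cluster 10 (4 and 15) and cluster 11 (1 and 0) of the authors' deposited tables. No gene was called in clusters 12 and 13, the smallest, where 95 and 102 genes had an unadjusted p under 0.05 in the authors' deposited tables. These clusters held 15 and 14 control-lineage nuclei, which may limit what could be called there, though this was not tested. The p-values appear to take nuclei as replicates, inferred from the arithmetic of the tables, so that they measure the spread between nuclei and not between fish.

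**Figure D1:**
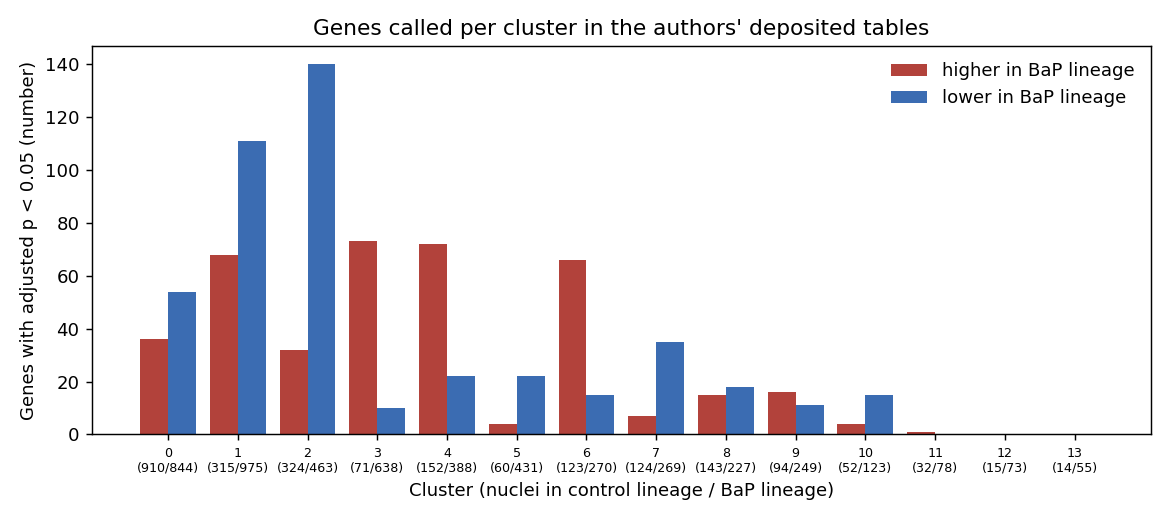
Number of genes (y axis) called higher (red) or lower (blue) in the BaP lineage in each of 14 clusters (x axis, with the nuclei of each lineage in parentheses), from the authors' deposited tables. Cluster 2 has 140 genes lower against 32 higher, and cluster 3 has 73 higher against 10 lower.

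Transcripts encoded by the mitochondrial genome were lower in BaP-lineage nuclei. All 13 protein-coding mitochondrial genes were called lower in at least 1 cluster of the authors' deposited tables, none was called higher, and these genes made 96 of the 453 lower calls (117 adjusted over the list alone). COX3, a subunit of cytochrome c oxidase, was lower in 10 clusters of the authors' deposited tables, with log2 fold changes from -0.63 in cluster 3 to -1.33 in cluster 10. ND2 and ND4 of complex I (-0.64 to -1.35 and -0.64 to -1.31), CYTB of complex III (-0.58 to -1.29), COX1 (-0.46 to -1.35) and ATP6 of the ATP synthase (-0.57 to -1.27) were lower in the same 10 clusters of the authors' deposited tables. COX2 was lower in 9 clusters, ND3 in 8, and ND1 and ND5 in 7 of the authors' deposited tables. ENSORLG00000021749 and ENSORLG00000021751, which have no symbol in the tables, were each lower in 9 clusters of the authors' deposited tables (-0.52 to -1.16 and -0.31 to -0.85). The median of the list lay below that of matched random lists in 12 of 14 clusters of the authors' deposited tables, with medians from -0.36 in cluster 13 to -1.29 in cluster 10, past the threshold after adjustment over 321 tests. In cluster 7, led by epithelial genes, the median of the authors' deposited table was -0.20 (percentile 5.69 among random lists) and in cluster 12 it was -0.01 (percentile 13.3). With the prior count taken out, the list was no longer past the threshold in cluster 13 (adjusted tail share 0.365, 10 members).

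Mitochondrially encoded transcripts made up 14.7% to 38.0% of UMIs in control-lineage nuclei and 6.05% to 35.6% in BaP-lineage nuclei, calculated from the authors' deposited tables. In cluster 1 the share was 17.5% against 8.26%, in cluster 10 it was 15.7% against 6.05%, and in cluster 7 it was 38.0% against 35.6%. Genes of the nuclear genome that encode parts of the same respiratory complexes, with their assembly factors, moved much less in the damped fold changes. None of the 91 in the tables was called in any cluster, and 8 calls, all lower, came with the p-values adjusted over the list alone. Their median was nevertheless below that of matched random lists in clusters 1, 5, 6, 9 and 13 of the authors' deposited tables, with medians between -0.04 and -0.13. With the prior count taken out the list was not past the threshold in clusters 5 and 6 (adjusted tail shares 0.338 and 0.104). Over fewer members, its medians were then -0.27, -0.65, -0.40, -0.51 and -1.75 in clusters 1, 5, 6, 9 and 13. Those of the mitochondrial list were -1.18, -0.99, -0.95, -0.85 and -0.35. Among these members the contrast was smaller, and it turned in cluster 13 (7 nuclear-encoded members against 10 mitochondrial ones). Only genes with at least 3 counts in each lineage entered, so the removal of damping could not be told apart from this choice of members.

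**Figure D2:**
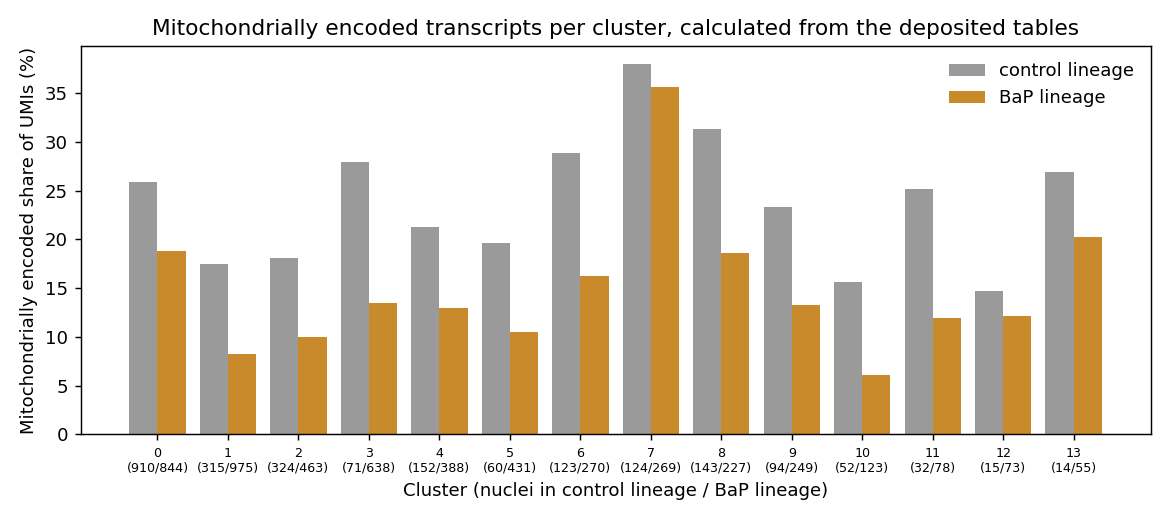
Share of UMIs from the 13 mitochondrially encoded genes (y axis, percent) in control-lineage nuclei (grey) and BaP-lineage nuclei (orange) of each cluster (x axis, with the nuclei of each lineage in parentheses), calculated from the authors' deposited tables. The BaP-lineage bar is the lower in all 14 clusters, from 6.05% against 15.7% in cluster 10 to 35.6% against 38.0% in cluster 7.

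Beyond the 13 mitochondrial genes above, a small set of genes was called in the same direction in many clusters. In total 21 genes were lower in 5 or more clusters of the authors' deposited tables, 10 of them among those 13, and 2 genes were higher, fkbp5 and NELL1. The other lower genes include ENSORLG00000021749 and ENSORLG00000021751, named above, which were lower in the same 9 clusters as COX2. They have no symbol, so whether the mitochondrial genome encodes them too is not known here. ENSORLG00000026256 (6 clusters, -0.96 to -1.96) and ENSORLG00000027445 (5 clusters, -0.69 to -2.48) were also among the lower genes, and they are leading genes of the erythrocyte-led cluster 8. Random placement of the calls among genes of like mean expression gave 0.0003 genes on average in either direction, and at most 1 in 10000 draws, although clusters share the same fish and are not independent. fkbp5, a co-chaperone of steroid receptors that glucocorticoids induce in vertebrates, was higher in clusters 1 to 6 of the authors' deposited tables, with log2 fold changes of 0.75, 0.52, 1.32, 1.12, 1.61 and 1.70. In the myelin-gene cluster 6, it had an adjusted p of 2.5e-11 in the authors' deposited table. NELL1, a secreted protein, was higher in clusters 0 to 4 of the authors' deposited tables (0.44 to 1.65). PNPLA6, a phospholipase known as neuropathy target esterase, was lower in clusters 0, 1, 2, 3, 7 and 8 of the authors' deposited tables, by -1.57, -0.85, -0.97, -1.27, -2.11 and -1.22. It was not called in the other clusters of the authors' deposited tables, where its values ran from -0.79 in cluster 12 to 1.41 in cluster 13. The histone deacetylase gene hdac9b was lower in 5 clusters of the authors' deposited tables (-0.68 to -1.19), as was the cyclin gene ccnl1a (-0.49 to -0.97), and nxt2, of the mRNA export machinery, in 4 (-0.64 to -1.23). RNaseP-nuc.1, an annotated RNA of nuclear RNase P, was lower in 5 clusters of the authors' deposited tables (-0.70 to -1.57). RAPGEF5 was lower in 6 clusters of the authors' deposited tables (-0.29 to -1.06), on no more than 62 counts in any of them. In cluster 11 of the authors' deposited table, the RNA-binding protein gene dazap1, also among its leading genes, was the sole call (1.31).

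Of 33 genes of the glutamatergic synapse in the tables, 7 were called higher in some cluster of the authors' deposited tables, none lower and 26 in no cluster, in 10 calls (46 higher and 0 lower adjusted over the list alone). The AMPA receptor subunit genes gria1a (0.53 in cluster 2, 0.95 in cluster 4) and gria3a (0.38, 0.47 and 0.59 in clusters 0, 1 and 4) were among them in the authors' deposited tables, with gria4a in cluster 2 (0.61) and gria4b in cluster 0 (0.42). The list's median lay above matched random lists in 5 of 14 clusters, 0, 1, 2, 4 and 10, of the authors' deposited tables, at 0.10, 0.21, 0.16, 0.32 and 0.39. With the prior count taken out it missed the threshold in clusters 4 and 10, with adjusted tail shares of 0.146 and 0.0740. With both lineages scaled to 1 total, the lower mitochondrial share alone would raise every other transcript by 0.13, 0.15, 0.14, 0.14 and 0.16 before damping. Matched random lists had medians of 0.02, 0.06, 0.01, 0.14 and 0.17 in these clusters, so they did not show that rise in clusters 0, 1 and 2. The mean levels worked out per lineage did not have equal totals, so that rise is a rough reference. Of 39 genes of voltage-gated ion channels, 7 were called higher and none lower in the authors' deposited tables (39 higher and 0 lower calls adjusted over the list alone). They included the sodium channel gene SCN8A in clusters 0, 1 and 3 (0.32, 0.52 and 1.38), the calcium channel genes CACNA1A in clusters 0 and 2 (0.35 and 0.49) and cacna1ab in clusters 1 and 4 (0.37 and 0.45), and the potassium channel gene KCND3 in cluster 1 (0.80) of the authors' deposited tables. This list's median was above matched random lists in clusters 0 and 1 of the authors' deposited tables (0.08 and 0.15), in cluster 1 not with the prior count taken out (adjusted tail share 0.0754).

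Among 62 genes of axon guidance and synaptic adhesion, 5 were called higher and 1 lower in the authors' deposited tables (38 higher and 2 lower calls adjusted over the list alone). The postsynaptic adhesion gene nlgn1 was higher in clusters 3, 4 and 9 (0.98, 0.83 and 0.84), TENM3 in clusters 0 and 6 (0.41 and 0.92), NCAM2 in cluster 3 (1.26) and opcml in cluster 6 (0.81) of the authors' deposited tables. The list's median was above matched random lists in clusters 4, 10 and 13 of the authors' deposited tables (0.25, 0.42 and 0.64). In clusters 4 and 13 it missed the threshold with the prior count taken out (adjusted tail shares 0.138 and 0.356), and in cluster 13 also by the mean (0.0959). Of 35 genes of presynaptic release, 5 were called higher and 1 lower in the authors' deposited tables, 16 and 2 adjusted over the list alone. The list's median was below matched random lists in cluster 9 of the authors' deposited table (-0.08). Examples in the authors' deposited tables were syt1a (1.08) and snca (0.98) in cluster 3, and BSN (0.42) and UNC13C (0.63) in cluster 1. Of 27 genes of the GABAergic synapse, 3 were higher and 1 lower in the authors' deposited tables (19 and 3 calls adjusted over the list alone), and the list's median passed the threshold in no cluster. They were nlgn2a in cluster 3 (1.30), nlgn2b in cluster 0 (0.37), gabbr2 in cluster 4 (0.55) and, lower, the GABA-degrading enzyme gene abat in clusters 1 and 2 (-0.37 and -0.52) of the authors' deposited tables.

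Ribosomal protein genes went in different directions between clusters. Of 72 in the tables, 15 were called lower, in 22 calls all in clusters 0, 1 and 2, and 5 were called higher, all in cluster 3 of the authors' deposited tables (48 lower and 34 higher calls adjusted over the list alone). Members lower in the authors' deposited tables were rpl17 in clusters 0, 1 and 2 (-0.43, -0.48 and -0.80), rpl31 in clusters 0 and 2 (-0.50 and -0.56), and rps2 in clusters 1 and 2 (-0.39 and -0.47). The list's median lay below matched random lists in clusters 0, 1, 2, 4, 6 and 13 of the authors' deposited tables (-0.13, -0.05, -0.24, 0.00, 0.02 and -0.03). It lay above them in cluster 3 of the authors' deposited table (0.63), where it was no longer past the threshold with the prior count taken out (adjusted tail share 0.19) or over members in the upper part of mean expression (0.0961). The list leaves out 9 S6 kinase genes, a choice made after the values were seen, and with them it passed in 5 clusters in place of 7, missing in clusters 3 and 6 (adjusted tail shares 0.0656 and 0.0773). In cluster 3, with 71 control-lineage against 638 BaP-lineage nuclei, the median of all genes in the upper part of mean expression was itself 0.25 in the authors' deposited table. That median was over 0.1 in 5 clusters of the authors' deposited tables, and the highest was 0.34, in cluster 13. Heat shock and unfolded protein response genes had a median below matched random lists in clusters 0, 1 and 2 of the authors' deposited tables (-0.06, -0.06 and -0.13), which did not hold with the prior count taken out (adjusted tail shares 0.131, 0.0575 and 0.104). In cluster 0 it also missed the threshold by the mean (0.0559), and in cluster 1 in the run with the S6 kinases in the ribosomal list (0.0613), where its random lists were drawn anew (percentile 0.41 against 0.31). hsp90aa1.2 and HSF1 were lower in cluster 2 (-0.66 and -0.49), and hsp90ab1 was higher in cluster 3 (0.67) of the authors' deposited tables.

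In the myelin-gene cluster 6, 4 of 20 detected myelin genes were called higher in the authors' deposited table and none lower (6 and 0 adjusted over the list alone). They included mpz, the major protein of fish myelin (0.88), ugt8, which makes the myelin lipid galactosylceramide (1.33), and the tight junction gene cldn19 (0.82) in the authors' deposited table. The list's median was 0.33 in the authors' deposited table (percentile 99.9), and missed the threshold with the prior count taken out (adjusted tail share 0.0575) and over members in the upper part of mean expression (0.0536). The mitochondrial share in this cluster was 28.8% in control-lineage and 16.2% in BaP-lineage nuclei by the authors' deposited table. With both lineages scaled to 1 total, that alone would raise every other transcript by 0.24 before damping. Matched random lists had a median of 0.08. mbpb, whose product compacts the myelin sheath, was not called there (0.27) and was lower in cluster 2 (-0.90) of the authors' deposited tables. Of the 30 genes that lead this cluster, 11 were called higher in the authors' deposited table, mpz, cldn19 and ugt8 among them. The myelin list's median was below matched random lists in cluster 1 (-0.05) and cluster 13 (-0.76) of the authors' deposited tables, with no member called there, in cluster 1 not by the mean (adjusted tail share 0.0800). In cluster 6, 28 detected genes of cholesterol synthesis and lipid handling had a median of 0.21 in the authors' deposited table, above all matched random lists. None was called, 2 were higher adjusted over the list alone, and with the prior count taken out the adjusted tail share was 0.401 over 10 members.

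**Figure D3:**
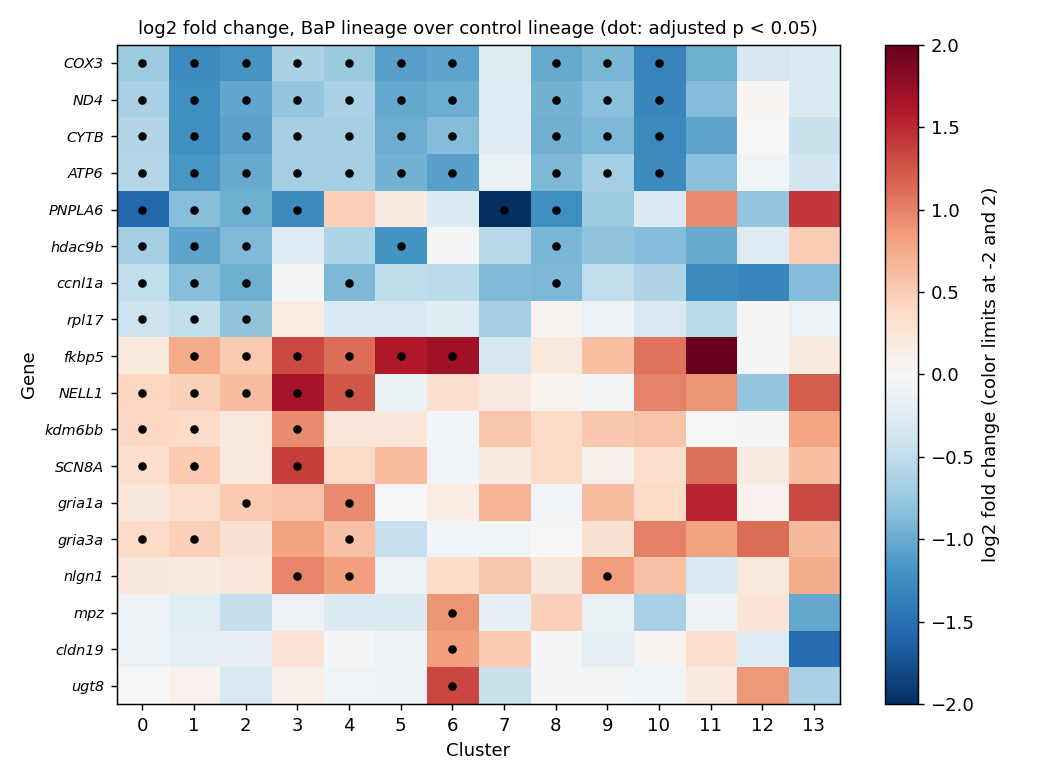
Log2 fold change of BaP lineage over control lineage (color) for 18 named genes (rows) in the 14 clusters (columns), from the authors' deposited tables, with a dot where the adjusted p was under 0.05. Colors end at -2 and 2. COX3, ND4, CYTB and ATP6 are lower in 10 clusters, fkbp5 is higher in 6, and PNPLA6 takes both signs, with dots at lower values alone.

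Several peptide hormone genes differed by large amounts. In cluster 1, oxt, the gene of the oxytocin family (isotocin in fish), was higher by 2.15, and oxt.1, a second gene model of that name, by 3.37 in the authors' deposited table. Reads shared between the 2 models could not be told apart, so their separate values are uncertain. oxt.1 was also higher in cluster 0 of the authors' deposited table (1.04). In cluster 2, pomca, the precursor of ACTH and melanocyte-stimulating hormone, was lower by -3.26, and in clusters 1 and 6 the feeding-related peptide gene cart4 was lower by -1.14 and -1.62 in the authors' deposited tables. pomca was called in no other cluster, and its values were above 0 in 11 of the 13 clusters in which it was detected, up to 1.49. oxt, oxt.1 and pomca are among the 30 leading genes of the clusters in which they were called. Values per nucleus are not used here, so a change within nuclei could not be told apart from a different mix of nuclei in a cluster. Over the 29 neuropeptide and pituitary hormone genes in the tables there were 1 higher and 3 lower calls, 4 and 6 adjusted over the list alone, in the authors' deposited tables. The list's median was below matched random lists in cluster 11 of the authors' deposited table (-0.50, 5 members), and not by the mean (adjusted tail share 0.0805). The glycosyltransferase gene galnt14 was higher in clusters 0, 1 and 2 of the authors' deposited tables, by 0.46 in cluster 0 and 0.89 in cluster 2. Other genes of large change in cluster 2 were pdxkb (0.72), sntg2 (0.72) and septin9b (0.69), and, lower, stxbp6l (-1.17) and prf1.5 (-1.09) in the authors' deposited table. prf1.5 is a leading gene of cluster 8, and it was also lower in clusters 0 and 1 of the authors' deposited tables (-0.54 and -0.62). In cluster 4, ELMO2 (1.22) was higher and mvp (-0.82) lower in the authors' deposited table.

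Genes of the response to BaP itself, as far as they could be matched by symbol, were not called. BaP acts through the aryl hydrocarbon receptor (AhR), which induces cyp1 genes, and none of 16 AhR pathway and xenobiotic metabolism genes was called in any cluster of the authors' deposited tables (1 higher and 0 lower adjusted over the list alone). cyp1a, detected in 9 clusters, had values between -0.01 and 0.33 and at most 31 counts per cluster in the authors' deposited tables. The receptor gene ahr1b had values between -0.26 and 0.51 on at most 30 counts. The genes ahr2 and ahrr were on the list but matched no symbol, so they were not assessed. The receptor's partner gene arnt (-0.31 to 0.36), cyp1b1 (-0.05 to 0.36, detected in 3 clusters) and cyp1c2 (-0.03 to 0.10, in 5) were not called in the authors' deposited tables. At this depth a small difference in these genes may have gone unseen, and what size could be called was not tested. The DNA methylation genes dnmt1 (-0.51 to 0.23), dnmt3aa (-0.75 to 1.35), dnmt3ba, dnmt3bb.1, dnmt3bb.2, TET1, TET2 and tet3 were likewise not called in the authors' deposited tables, and the smallest adjusted p among them was 0.0627, for tet3. Of 37 DNA methylation and chromatin regulator genes, 1 was called higher and 3 lower in the authors' deposited tables (5 and 11 calls adjusted over the list alone). The histone demethylase gene kdm6bb was higher in clusters 0, 1 and 3 (0.42, 0.38 and 0.95), and hdac9b, suz12a (-0.61 in cluster 2) and SMARCA2 (-0.46 in cluster 2) were lower in the authors' deposited tables.

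Among the remaining lists, calls were few. The oxidative stress list (24 genes) had 0 higher and 2 lower calls in the authors' deposited tables (2 and 8 adjusted over the list alone), immediate early genes (22) 0 and 1 (0 and 2), and circadian clock genes (36) 3 and 0 (5 and 1). Innate immunity genes (32) had 0 and 1 calls in the authors' deposited tables (2 and 2 adjusted over the list alone), cell cycle and neurogenesis genes (39) 0 and 1 (1 and 2), and heat shock genes (29) 1 and 2 (2 and 11). In the authors' deposited tables prdx5 (-0.52) and sqstm1 (-0.55) of the oxidative stress list and the antigen presentation gene cd74a (-0.45) were lower in cluster 1, and bdnf (-0.60) and stmn1a (-0.56) were lower in cluster 2. The circadian genes ciarta in cluster 6 (1.03), clockb in cluster 3 (1.38) and csnk1db in cluster 1 (0.50) were higher in the authors' deposited tables. No member of the lists for DNA damage response (32 genes), monoamine and acetylcholine systems (43), sex steroid signalling (22), cholesterol and lipid handling (38) or the thyroid hormone axis (12) was called in the authors' deposited tables. Adjusted over the list alone, these gave 0, 2, 1, 5 and 3 calls. The median of immediate early genes in cluster 11 (-0.41, 6 members) and of oxidative stress genes in cluster 0 (-0.03) was below matched random lists in the authors' deposited tables, the latter not with the prior count taken out (adjusted tail share 0.26), by the mean (0.152) or over members in the upper part of mean expression (0.153).

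Across genes, log2 fold changes of different clusters were weakly and positively related. The Spearman correlation over genes in the upper part of mean expression had a median of 0.13 over the 91 pairs of clusters of the authors' deposited tables, from 0.03 between clusters 12 and 13 to 0.35 between clusters 0 and 1. Genes are not independent replicates, and the clusters hold nuclei of the same 6 fish, so that a difference of 1 fish would also appear in several clusters.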

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

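The alternatives without mitochondrially encoded genes, without clusters 0 and 7, with the prior count taken out and with the S6 kinases were chosen only after the result was seen. No paired analysis was possible because the authors' tables hold no values per fish, and for the same reason leave-one-out, other count models, size factors, count filters and pseudocounts were not run. A single fish could therefore set any difference. Clusters 11, 12 and 13 held 110, 88 and 69 nuclei, and mean depth was lowest in cluster 0 (684 UMIs).

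At an adjusted p under 0.01 the authors' deposited tables held 208 higher and 301 lower calls (56, 99, 95, 43, 60, 17, 27 and 0 in clusters 0, 1, 2, 3, 4, 5, 7 and 11), and under 0.1 they held 606 higher and 577 lower (159 in cluster 3, 67 in cluster 7). An absolute log2 fold change of at least 0.5 left 30 and 119 calls in clusters 0 and 1. At least 1 left 131 higher and 98 lower calls (2, 20, 11, 7, 17, 30, 16 and 15 in clusters 0, 1, 2, 4, 5, 6, 8 and 9), 57.2% of them higher against 46.5% of all calls. Adjustment over all clusters together gave 5 calls in cluster 11. Without mitochondrially encoded genes 394 higher and 357 lower calls were left (52.5% higher), 16 and 10 in clusters 5 and 10. The excess of lower calls thus turned under these genes' removal, an adjusted p under 0.1 and a fold change of at least 1; in cluster 8 it turned from 15 higher and 18 lower to 15 and 8, 20 and 18, and 12 and 4, and to 20 and 18 with adjustment over detected genes. These changes follow from stricter or looser thresholds or fewer genes. Recomputing the adjustment changed no call, and adjusting over detected genes gave 488 higher and 509 lower calls.

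In 3 or more clusters, 16 genes were higher and 41 lower, and in 8 or more 0 and 10. Higher in 5 or more was 1 gene at an adjusted p under 0.01, 1 with a fold change of at least 0.5 and 1 without clusters 0 and 7. Lower were 11 without the 13 listed mitochondrially encoded genes, with ENSORLG00000021749 and ENSORLG00000021751 still counted. The median correlation between clusters was 0.104 over all detected genes, 0.235 over the genes of highest mean expression and 0.162 by Pearson, and its cause was not tested. Of 45 list tests past the threshold, centring kept 45 (by construction), the mean 40 and the S6 kinases 42; members of higher expression kept 40 of 43. With the prior count taken out 27 of 42 were kept, and 6 tests were past the threshold higher against 13 before, with fewer members per list. The leading cell type was the same in 8 of 14 clusters with control-lineage means and in 9 with the median of other clusters, and the cause was not tested. No list test reversed its direction.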

Other observations

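The tests of free cytoplasmic RNA, of fkbp5 scaling, of glucocorticoid targets and of 2 patterns against the rise from the mitochondrial share, and the genes gkup, CSPG5, gapdhs, safb, hbbe2 and glula, were chosen only after the result was seen.

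Further genes were called in several clusters of the authors' deposited tables. gkup was higher in clusters 5, 6, 8 and 9 (1.21 to 1.75), and CSPG5, a brain proteoglycan gene, in clusters 0, 3, 4 and 10 (0.39 to 1.27) of the authors' deposited tables. gapdhs, of glycolysis, was lower in clusters 0, 1, 2 and 5 (-0.57 to -0.87), and safb, of a nuclear matrix protein, in clusters 0, 1, 2, 4 and 5 (-0.53 to -1.07) of the authors' deposited tables. The embryonic-type globin gene hbbe2, a leading gene of cluster 8, was lower in clusters 0, 1 and 7 of the authors' deposited tables (-0.92, -0.89 and -1.73). The glutamine synthetase gene glula was lower in clusters 0 and 2 (-0.58 and -0.73) and higher in cluster 6 (0.82) of the authors' deposited tables.

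Mitochondrially encoded transcripts in nuclei come from the cytoplasm, so their lower share may reflect cleaner BaP-lineage nuclei. More free cytoplasmic RNA of every kind in control-lineage libraries would lower ribosomal protein transcripts as well. Their median was below 0 in 5 of the 12 clusters with a mitochondrial median under -0.3 (4 with the S6 kinases). It was below the rise that the lower mitochondrial share would give other transcripts in 9 of 12. That rise assumes equal totals in both lineages, which the mean levels worked out here did not have. In cluster 0, 196 mitochondrial UMIs made 25.9% of the control-lineage total and 131 made 18.8% of the BaP-lineage total. In cluster 3, 332 made 27.9% and 209 made 13.5%. The total was thus lower in BaP-lineage nuclei of cluster 0 and higher in those of cluster 3. More free cytoplasmic RNA stays open. A pool of free mitochondrial RNA adding the same amount to every nucleus predicts a loss that varies less between clusters than the log2 ratio, and the ratio of their coefficients of variation was 0.976 (0.459 against 0.470), on the predicted side but within a margin asked for after that value was seen. A strictly equal amount would give 1 loss, and the losses ran from 8.04 to 245 UMIs per nucleus (65.6 in cluster 0, 210 in cluster 2). They were worked out from fold changes whose scaling between lineages is not stated. Depth per lineage is unknown, so an equal amount stays open too. Carry-over of mitochondria with the nuclei of some fish and a lineage difference are untested.

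Genes that lead a cluster were often higher in BaP-lineage nuclei: over all clusters, 35 calls of such genes were higher and 9 lower, 11 of the higher in cluster 6. Less RNA of other cell types in BaP-lineage nuclei could do this: leading genes of the other clusters had a pooled ratio below 0 in 7 of 14 clusters (2 without the leading genes of clusters 7 and 8), which met the bound written beforehand against it. That bound took 0 as no change. The ratio was below the rise from the mitochondrial share in 11 of 14 (7 without those genes). This comparison was chosen afterwards and assumes equal totals in both lineages, which the worked-out mean levels did not have. In cluster 2 the median of all genes of upper expression was -0.007, against a rise of 0.14 before damping. Neither comparison settles it, so the explanation stays open and rests on the leading genes of clusters 7 and 8. Choosing leading genes with both lineages weighted equally left the median above 0 in 10 of 14 clusters, which met the bound written beforehand against a choice effect, and left 26 calls higher and 4 lower (11 and 0 in cluster 6). That bound was a weak one, a reading made after the values were seen, since the median of all genes of upper expression was itself above 0 in 12 clusters and only 8 of 14 medians passed the 50th percentile of matched genes. A lineage difference is untested.

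fkbp5 could rise merely because less mitochondrial RNA enters the total to which nuclei are scaled. In clusters 1, 3, 4, 5 and 6 it exceeded that rise, again worked out for equal totals, by at least 0.59. In cluster 2 it did so by 0.38, under the bound of 0.5. The clusters were parted after these values were seen. A glucocorticoid-type response predicts that other known target genes rise as well. Their median lay in the upper tail of random lists in 2 of the 6 clusters where fkbp5 was called (percentiles 98.2 in cluster 5 and 99.4 in cluster 6), against 96.6 in cluster 3, 93.0 in cluster 4, 36.0 in cluster 1 and 2.06 in cluster 2. In cluster 2, 3 target genes were called lower (ddit4, glula and mt2) and none higher. In cluster 6, glula and zbtb16a were called higher, and in clusters 1, 3, 4 and 5 no target was called. Where fkbp5 was not called, glula and mt2 were lower in cluster 0 and zbtb16a was higher in cluster 9. Such a response may apply to part of the clusters. A median over damped fold changes cannot exclude it in the rest, although cluster 2 leaned the other way. Whether 1 fish, its state at sampling or the lineage set such a response cannot be seen without values per fish.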
